A study of Mus musculus with 12 samples.

How the data were processed

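RNA from the spinal cord of wild-type female C57BL/6 mice aged 10 weeks was measured on 12 Affymetrix arrays, which fall into 4 groups of 3 biological replicates (total RNA and polysome-bound RNA, each from sham-operated and from injured cord). Per the labels, biotin-labelled cRNA was made in a one-cycle reaction from 5 µg of total RNA or 3 µg of polysome-bound RNA. The sample titles call the control cords naive, whereas the design and treatment notes describe a sham operation; they are called sham here. The deposited values are log2 expression values, with 1 summarised value per probe set and array; the labels do not name the scale, which was read from the range of 5.26 to 14.65. The authors' background correction and normalization are not given, and the arrays were not brought to a common distribution, since their medians differ between the fractions. The values were used as deposited. Raw intensities were not used here.

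The table held 22690 probe sets. Of these, 20393 named 1 gene and were used, 691 named several genes and 1606 named none, among them 64 control probe sets that served only for array quality. Symbols were taken from the annotation supplied with the array, and 20364 of the named probe sets had a symbol present in the RefSeq gene table of mouse assembly GRCm38.p6. Probe sets were kept if they exceeded the 25th percentile of the array on at least 3 arrays, which left 18042. Each gene was represented by its brightest probe set, and 10371 genes were tested; 3989 of them had 2 or more probe sets. Depth has no direct counterpart on arrays: the number of arrays limits the precision, and signal near the absent-control probe sets carries little information.

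Differences were estimated with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with a mean for each of the 4 groups, 8 residual degrees of freedom and empirical Bayes moderation with an intensity trend, which gave 14.1 degrees of freedom. All p values were two-sided and were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. There were 5 comparisons: injured against sham in total RNA, the same in polysome-bound RNA, the difference between those changes (the interaction of operation and fraction), and polysome-bound against total RNA within sham and within injured cord. Errors given for log2 changes are limma standard errors from 3 arrays a group. Group means are given with the SD over 3 arrays. Single array measures were compared by exact two-sided permutation tests, which cannot fall below 0.1 with 3 arrays against 3.

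Across genes, 37 lists of pathway, cell type and complex genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were run beside it. Some lists share genes, so the calls of such lists are not independent. The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took, among genes past the threshold whose groups did not overlap on any array, the 10 largest rises and 10 largest falls of each injury comparison and of the interaction (there, differences of equal-numbered samples), the 5 largest each way for the fraction comparisons, up to 4 members of each list with the lowest adjusted p, and Cpeb1, Cpeb2, Cpeb3 and Cpeb4. Clone and predicted-model names were skipped.

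The alternatives were no filter and a filter at the array median, the mean of a gene's probe sets and each probe set on its own, quantile normalization over 12 arrays or within each fraction, centring of arrays on their median, an added minimum log2 change of 1, other ways of moderating the spread, array weights, a spread from the compared groups alone, 2 ways of using the replicate number as a block, and leaving out each array. Leaving out each array repeated the choice of the brightest probe set. The exclusion of probe sets whose names end in _s_at or _x_at, the leaving out of arrays with the probe sets kept as first chosen, and the count of genes called alike as deposited, after centring and after quantile normalization, were chosen after seeing the data. The replicate numbers are shared by the groups, but the labels do not say that equal numbers mark the same animal, so no block was used in the values reported first. A planned analysis of polyadenylation element motifs in 3′ untranslated regions was left out, because no sequence was available.

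The procedure was tested on simulated data with the spread of these arrays and 50 changed genes of each size. In total RNA it recovered 42% of changes of 0.25 on the log2 scale, 94% of changes of 0.5 and 100% of changes of 1, with 4% false calls. For the interaction it recovered 10%, 60% and 96%. The simulated noise was independent between genes, few genes were changed and no array-wide shift was added. Each gene also had the same simulated spread on all arrays, whereas the real injured polysome arrays varied more within their group than the others. The shares of recovered changes and of false calls in the real data may therefore differ. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.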

Results

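The series held 12 arrays of RNA from the spinal cord of adult female mice, with 3 biological replicates in each of 4 groups. One set of mice had a transection of 80% of the cord and the other a laminectomy alone (sham), and 2.5 cm of cord around the site was taken 9 hours later. An aliquot of each Dounce homogenate gave total RNA, and the remainder was run on a sucrose gradient to collect RNA bound to polysomes, that is, mRNA loaded with several ribosomes. The series title names Cpeb1, a protein that binds cytoplasmic polyadenylation elements in the 3′ ends of mRNAs and regulates their translation. The comparisons ask which transcripts changed in amount after injury, which changed on polysomes, and where these changes differed. Genes are given by symbol, and single-gene changes are log2 differences of the deposited values with the limma standard error (SE) from 3 arrays a group.

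Arrays of a group correlated across genes, which are not independent replicates, at 0.994 to 0.998. Array weights estimated from the spread were 0.21 and 0.47 for injured polysome replicates 1 and 2, against 0.89 to 2.08 for the other arrays. The median log2 value of an array averaged 7.76 ± 0.01 in sham total RNA, 7.78 ± 0.02 in injured total RNA, 7.25 ± 0.01 in sham polysome-bound RNA and 7.18 ± 0.06 in injured polysome-bound RNA (mean ± SD, n = 3). Probe sets for organisms absent from the sample, a measure of background, had medians of 6.08 ± 0.01, 6.06 ± 0.02, 5.70 ± 0.02 and 5.71 ± 0.02 in the same order. Gapdh, a glycolytic enzyme gene, has control probe sets at both ends. The 3′ minus 5′ difference was 0.23 ± 0.05 in sham and 1.40 ± 0.22 in injured total RNA, and 0.87 ± 0.03 in sham and 2.83 ± 0.27 in injured polysome-bound RNA. The injured and sham arrays did not overlap in either fraction (exact permutation p = 0.1 each, the smallest that 3 against 3 allows). For Actb, which encodes beta-actin, that difference went from 1.46 ± 0.07 to 1.80 ± 0.07 in total RNA and from 1.68 ± 0.10 to 3.26 ± 0.48 in polysome-bound RNA. It changed by 0.29 and -0.04 for Pcx and by -0.21 and -0.04 for Tfrc.

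**Figure D1:**
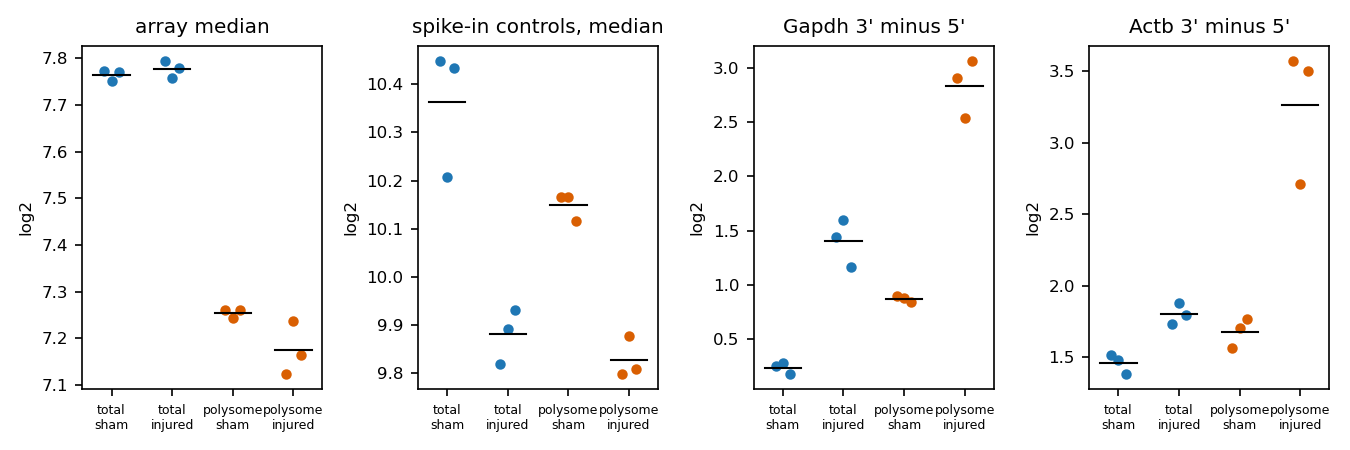
Quality measures of the 12 arrays in log2 units: the median of all probe sets, the median of the spike-in controls, and the 3′ minus 5′ difference of Gapdh and of Actb. Points are single arrays (blue, total RNA; orange, polysome-bound RNA) and lines are group means; Gapdh averaged 2.83 in injured polysome-bound RNA against 0.23 in sham total RNA.

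Cpeb1 was measured by 1 probe set and lay well above background in all groups, at 8.86 ± 0.09 in sham total RNA, 9.12 ± 0.09 in injured total RNA, 8.98 ± 0.08 in sham polysome-bound RNA and 8.64 ± 0.22 in injured polysome-bound RNA (mean ± SD, n = 3). Its transcript was 0.26 higher after injury in total RNA (SE 0.09, limma adjusted p = 0.029) and fell by 0.33 on polysomes (adjusted p = 0.011). The change on polysomes was thus 0.59 below that in total RNA, an interaction of -0.59 (SE 0.13, adjusted p = 0.0026). After quantile normalization the rise in total RNA was 0.08 and the interaction -0.29, neither past the threshold. Without sham polysome replicate 1 the fall on polysomes was -0.29 and missed it, and the rise in total RNA missed it without sham total replicate 1 or 2 or injured total replicate 3 (0.21, 0.26 and 0.21). Among its paralogs, Cpeb2 rose by 0.30 (SE 0.07) in total and 0.24 (SE 0.07) in polysome-bound RNA, and Cpeb4 rose by 0.37 (SE 0.09) in total RNA. The polysome rise of Cpeb2 was not called without sham polysome replicate 2 or 3 (0.21 and 0.22). The total RNA rises were 0.03 and 0.08 after quantile normalization and no longer called. Cpeb3 was 0.39 higher on polysomes (SE 0.11, adjusted p = 0.014), with -0.19 (adjusted p = 0.16) in total RNA and an interaction of 0.58 (SE 0.16, adjusted p = 0.009). Its other 2 probe sets gave 0.03 and 0.21 on polysomes, and its rise there was not called without injured polysome replicate 2 (0.26) or without sham polysome replicate 2 or 3 (0.35 and 0.36). Of the 16 cytoplasmic polyadenylation factors measured, 10 rose and 0 fell in total RNA (10 and 0 adjusted over the list alone, camera adjusted p = 0.12). On polysomes 5 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.503 with an estimated correlation), and the list was not called without 1 injured polysome array (adjusted p = 0.0742). Pabpc1, the poly(A)-binding protein gene, rose on polysomes by 0.59 (SE 0.08) and Cpsf1, a cleavage and polyadenylation subunit, by 0.34 (SE 0.07).

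In total RNA, the largest rises 9 hours after injury included several acute phase and STAT3-linked genes. Socs3, a feedback inhibitor of cytokine signalling, rose 12.8-fold (log2 3.68, SE 0.21, limma adjusted p = 4.9e-08), from 7.14 ± 0.20 to 10.82 ± 0.38 (mean ± SD, n = 3). Large rises were also seen for the protease inhibitors Tfpi2 (3.57, SE 0.33), Serpina3n (2.97, SE 0.12) and Timp1 (2.47, SE 0.29), and for Lcn2 (3.01, SE 0.33), which binds bacterial iron carriers. Tfpi2 was above every absent control on 0 of 3 sham and 3 of 3 injured total RNA arrays, so the size of its rise and its rank are not determined. The small heat shock protein gene Hspb1 rose by 2.87 (SE 0.11), the lipid droplet protein gene Plin4 by 2.69 (SE 0.15), the chemokine gene Ccl6 by 2.65 (SE 0.26), the transcription factor gene Cebpd by 2.60 (SE 0.15) and the proteoglycan gene Srgn by 2.45 (SE 0.28). A second probe set of Cebpd gave 0.10 and was not called.

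The largest falls in total RNA were smaller. Mapk8ip1, a scaffold of JNK signalling, fell by 1.21 (SE 0.16, limma adjusted p = 3.5e-05), Rph3a, a synaptic vesicle effector, by 1.16 (SE 0.15), the teneurin gene Tenm4 by 1.13 (SE 0.12) and Sult4a1, a sulfotransferase gene of neurons, by 1.11 (SE 0.16). The next falls were those of Evi5 (-1.11, SE 0.11), Efcab14 (-1.10, SE 0.11), Tprkb (-1.09, SE 0.10), Wdfy3 (-1.08, SE 0.14), Psg28 (-1.06, SE 0.11) and Mtm1 (-1.03, SE 0.11). Other probe sets disagreed for Evi5 (0.43) and for Mtm1 (-1.36 and 0.45).

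Injury in total RNA raised several lists of genes, given here with the list median minus the median change of all genes, 0.12. All 16 acute phase and STAT3-linked genes rose (16 adjusted over the list alone; median 1.51 above all genes), among them the metallothionein gene Mt2 (1.69, SE 0.07). Camera gave an adjusted p = 1.2e-08, and adjusted p = 0.32 with an estimated correlation. Of 21 reactive astrocyte genes 20 rose and 0 fell (20 and 0 adjusted over the list alone). Their median was 1.29 above all genes (adjusted p = 1.5e-08, adjusted p = 0.32 with an estimated correlation), with the oncostatin M receptor gene Osmr at 2.41 (SE 0.14) and the endotoxin co-receptor gene Cd14 at 2.27 (SE 0.14). This list is not separate from the others: Osmr, Lcn2, Serpina3n and Timp1 are also acute phase members, and Cd14 is also a monocyte and macrophage marker here. All 11 glucocorticoid-induced genes rose (11 adjusted over the list alone). The list median was 1.31 above all genes (adjusted p = 3e-07, adjusted p = 0.0552 with an estimated correlation), with Fkbp5 at 2.15 (SE 0.13) and Cdkn1a at 1.83 (SE 0.11). Of 15 monocyte and macrophage markers 13 rose and 0 fell (14 and 0 adjusted over the list alone). This list's median was 0.96 above all genes (adjusted p = 2.1e-05, adjusted p = 0.33 with an estimated correlation), with the chemokine receptor gene Ccr1 at 1.61 (SE 0.13), and 40% of this list's genes lay above the absent controls. Of 18 cytokines and chemokines 16 rose and 2 fell (16 and 2 adjusted over the list alone). Here the median was 0.55 above all genes (adjusted p = 0.00089, adjusted p = 0.41 with an estimated correlation), with Cxcl2 at 2.42 (SE 0.16) and Ccl2 at 1.48 (SE 0.17). Cxcl2 did not exceed the absent controls on any sham array, so the size of its rise is not determined. Of 25 immediate early and AP-1 genes 18 rose and 4 fell (18 and 4 adjusted over the list alone). The median stood at 0.49 above all genes (adjusted p = 0.0044, adjusted p = 0.55 with an estimated correlation), with Fos at 1.76 (SE 0.15). Endothelial activation and proteolysis genes rose in 8 of 10 cases and fell in 0 (8 and 0 adjusted over the list alone). As a list their median was 0.63 above all genes (adjusted p = 0.011, adjusted p = 0.42 with an estimated correlation), with the prostaglandin synthase gene Ptgs2 at 2.04 (SE 0.18). Ptgs2 lay at background on all arrays of at least 1 of the 4 groups, so the size of this rise may not be determined. These 7 lists kept their calls after quantile normalization.

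Regeneration-associated genes, many of which neurons switch on after axon damage, rose in 18 of 21 cases and fell in 0 (18 and 0 adjusted over the list alone). For this list the median was 0.41 above all genes (camera adjusted p = 4.7e-05, adjusted p = 0.38 with an estimated correlation). Hspb1, Socs3 and Cebpd, above, are members. Stat3 itself was 1.19 higher (SE 0.07). Without any 1 of the injured total RNA arrays another of its probe sets was the brightest and gave 0.28 to 0.36, not called, whereas the first one kept gave 1.14 to 1.23, called each time. Hypoxia and glycolysis genes rose in 11 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone). Their median was 0.41 above all genes (adjusted p = 0.0026, adjusted p = 0.32 with an estimated correlation), with the heme oxygenase gene Hmox1 at 1.72 (SE 0.08) and the glucose transporter gene Slc2a1 at 1.06 (SE 0.08). Of 13 heat shock genes 10 rose and 0 fell (10 and 0 adjusted over the list alone). The list median was 0.27 above all genes (adjusted p = 0.0044, adjusted p = 0.32 with an estimated correlation). Of 15 integrated stress response genes 12 rose and 2 fell (12 and 2 adjusted over the list alone). This list's median was 0.21 above all genes (adjusted p = 0.046, adjusted p = 0.55 with an estimated correlation). The heat shock list was not called after quantile normalization (adjusted p = 0.12), and the stress response list not without each of 5 single arrays (adjusted p = 0.0524 to 0.0602). Astrocyte markers rose in 10 of 15 cases and fell in 0 (10 and 0 adjusted over the list alone). Here the median was 0.12 above all genes (adjusted p = 0.014, adjusted p = 0.54 with an estimated correlation), with the gap junction gene Gjb6 at 0.93 (SE 0.09); after quantile normalization the adjusted p was 0.24.

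Genes of the translation and protein turnover machinery were slightly higher in injured total RNA. Brighter genes in general were higher there too, with a deposited median change of -0.15 for the dimmest 1038 genes and 0.27 for the brightest 1037. As deposited, 36 of 43 cytosolic ribosomal protein genes (36 adjusted over the list alone), 14 of 14 translation elongation and other TOP genes (14 adjusted over the list alone), 29 of 37 proteasome genes (31 adjusted over the list alone) and 53 of 77 respiratory chain genes (54 adjusted over the list alone) were higher, and 0, 0, 0 and 3 were lower. Camera adjusted p was 0.00011, 0.00076, 4.7e-05 and 0.006 in that order, and adjusted p = 0.56, 0.33, 0.42 and 0.72 with an estimated correlation. After quantile normalization the list medians were 0.08, 0.07, 0.08 and -0.01. The ribosomal list kept its call (adjusted p = 0.034). The elongation and proteasome lists did not (adjusted p = 0.12 each), and the respiratory chain list turned to a lower direction (adjusted p = 0.3).

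Lists of homeostatic microglia, axon guidance and synaptic genes were called lower in injured total RNA, while neuron markers were not. Of 9 homeostatic microglia markers 6 fell and 0 rose (6 and 0 adjusted over the list alone). The median stood at -0.43 relative to all genes (camera adjusted p = 8.3e-05, adjusted p = 0.0552 with an estimated correlation), with the fractalkine receptor gene Cx3cr1 at -0.91 (SE 0.09) and the purinergic receptor gene P2ry12 at -0.66 (SE 0.09). Of 41 axon guidance and nervous system development genes 14 fell and 7 rose (14 and 7 adjusted over the list alone). As a list their median was -0.15 relative to all genes (adjusted p = 0.0021, adjusted p = 0.42 with an estimated correlation), with the growth factor receptor gene Fgfr2 at -0.80 (SE 0.07). Of 22 synaptic receptors and ion channels 9 fell and 7 rose (10 and 7 adjusted over the list alone). For this list the median was -0.25 relative to all genes (adjusted p = 0.014, adjusted p = 0.56 with an estimated correlation). The potassium channel genes Kcnc1 (-0.90, SE 0.12) and Kcna2 (-0.80, SE 0.06) fell. Lymphocyte (6 of 7), ependymal (5 of 5) and skeletal muscle (1 of 10) markers fell with 0 rises (6, 5 and 0 adjusted over the list alone), at camera adjusted p = 0.00094, 0.012 and 0.015 and adjusted p = 0.22, 0.32 and 0.56 with an estimated correlation. None of these 3 was called after quantile normalization (adjusted p = 0.32, 0.079 and 0.35), and 29%, 60% and 10% of their genes lay above the absent controls. Neuron markers went both ways, 11 higher and 5 lower (11 and 5 adjusted over the list alone, adjusted p = 0.93), with the synaptic vesicle gene Syt1 at -0.94 (SE 0.09) and the nuclear splicing factor gene Rbfox3 at -0.83 (SE 0.08).

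Limma called 6242 of 10371 genes in total RNA, 4369 higher and 1873 lower (60.2% of genes), and 132 rose and 15 fell at least 2-fold. The arrays of the groups did not overlap for 72.7% of genes, where chance gives 10%. Among genes with 2 or more probe sets, 2186 were called higher by the brightest, and the second was higher for 47.3% and lower for 18.3%. For 399 called lower it was lower for 60.9% and higher for 9.8%. The split depended on the scaling, with 70.0% of calls higher as deposited, 55.9% after quantile normalization, 56.0% within fractions and 40.1% after median centring. Altogether 1667 genes were higher and 976 lower in each of deposited, quantile and centred values. These changes in total RNA moved with the Gapdh 3′ minus 5′ difference, which was 1.17 greater after injury. The other controls changed by 0.34 for Actb, 0.29 for Pcx and -0.21 for Tfrc. Camera called 22 of 37 lists, and none of these calls held with an estimated correlation. By limma, 6707 genes had an unadjusted p under 0.05.

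On polysomes, the largest rises after injury included several glucocorticoid-induced and acute phase genes. Cebpd rose 6.25-fold (log2 2.64, SE 0.15, limma adjusted p = 4.1e-08), from 7.93 ± 0.29 to 10.57 ± 0.24 (mean ± SD, n = 3). Plin4 rose by 2.51 (SE 0.15), Socs3 by 2.38 (SE 0.21), the cell cycle inhibitor gene Cdkn1a by 2.01 (SE 0.11), the sulfotransferase gene Sult1a1 by 2.01 (SE 0.09) and Hspb1 by 2.00 (SE 0.11). The GTPase gene Rhoj (1.92, SE 0.18), the pentraxin gene Ptx3 (1.91, SE 0.17) and the serum amyloid genes Saa1 (1.78, SE 0.22) and Saa3 (1.77, SE 0.21) completed the largest rises. Ptx3 and Saa1 exceeded every absent control on 1 and 0 of 3 sham arrays, so the sizes of their rises and their ranks are not determined.

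The largest falls on polysomes included genes of myelin and astrocytes. The myelin membrane gene Pllp fell by 1.80 (SE 0.09, limma adjusted p = 2.5e-08), the protease inhibitor gene Serpinb1a by 1.69 (SE 0.09), Ugt8a, which makes the myelin lipid galactosylceramide, by 1.42 (SE 0.07) and the orphan receptor gene Gpr37 by 1.42 (SE 0.08). The astrocyte water channel gene Aqp4 fell by 1.21 (SE 0.06), from 11.20 ± 0.09 to 9.99 ± 0.10, and the fatty acid binding protein gene Fabp7 by 1.28 (SE 0.16). ND5, which is encoded and translated in mitochondria, fell by 1.56 (SE 0.10). Kcnip1 (-1.28, SE 0.07), Rabif (-1.20, SE 0.11) and Get3 (-1.19, SE 0.10) were the other large falls.

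Lists called higher on polysomes are given against an all-gene median change of -0.04. All 11 glucocorticoid-induced genes rose (11 adjusted over the list alone). Their median was 1.15 above all genes (camera adjusted p = 5.6e-14), and this call alone held with an estimated correlation (adjusted p = 0.011); Klf9 rose by 0.77 (SE 0.05). Of 16 acute phase and STAT3-linked genes 15 rose and 0 fell (16 and 0 adjusted over the list alone). The list median was 1.38 above all genes (adjusted p = 2e-14, adjusted p = 0.21 with an estimated correlation), with Stat3 at 1.07 (SE 0.07). Reactive astrocyte genes rose in 17 of 21 cases and fell in 0 (18 and 0 adjusted over the list alone). This list's median was 0.71 above all genes (adjusted p = 9.5e-13, adjusted p = 0.2 with an estimated correlation). Monocyte and macrophage markers went both ways, 8 of 15 higher and 2 lower (10 and 2 adjusted over the list alone). Here the median was 0.47 above all genes (adjusted p = 0.00074, adjusted p = 0.5 with an estimated correlation). The clotting factor gene F13a1 rose by 0.96 (SE 0.07) and the lysozyme gene Lyz2 fell by 1.04 (SE 0.12). Of 25 immediate early and AP-1 genes 17 rose and 0 fell (17 and 0 adjusted over the list alone, adjusted p = 9.3e-09, adjusted p = 0.41 with an estimated correlation), with Junb at 1.16 (SE 0.15). Of 18 cytokines and chemokines 11 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 3e-05, adjusted p = 0.43 with an estimated correlation), with Ccl12 at 1.60 (SE 0.28). Of 21 regeneration-associated genes 12 rose and 2 fell (13 and 3 adjusted over the list alone, adjusted p = 4.4e-06, adjusted p = 0.44 with an estimated correlation).

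Weaker calls were made on polysomes for heat shock genes (3 higher, 2 lower of 13; 3 and 2 adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.5 with an estimated correlation), integrated stress response genes (4 and 0 of 15; 4 and 0 adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.5 with an estimated correlation) and endothelial activation genes (3 and 1 of 10; 7 and 1 adjusted over the list alone, adjusted p = 0.04, adjusted p = 0.56 with an estimated correlation). Slc3a2, an amino acid transporter gene, rose by 0.56 (SE 0.08), the adhesion molecule gene Vcam1 fell by 0.51 (SE 0.09), and the protease gene Adamts1 rose by 0.81 (SE 0.17). After quantile normalization the heat shock and endothelial lists were not called (adjusted p = 0.28 and 0.14). Without 1 array the adjusted p reached 0.106 for heat shock, 0.0742 for stress response and 0.116 for endothelial activation genes.

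Lists of cholesterol synthesis, oligodendrocyte and homeostatic microglia genes were called lower on polysomes. Of 19 cholesterol synthesis genes 8 fell and 0 rose (11 and 0 adjusted over the list alone). The median stood at -0.15 relative to all genes (camera adjusted p = 0.0036, adjusted p = 0.6 with an estimated correlation), with Fdps at -1.18 (SE 0.06), Nsdhl at -0.92 (SE 0.07) and Dhcr7 at -0.91 (SE 0.07). Of 13 oligodendrocyte and myelin genes 5 fell and 1 rose (5 and 1 adjusted over the list alone). As a list their median was -0.14 relative to all genes (adjusted p = 0.043, adjusted p = 0.6 with an estimated correlation), with Aspa, an aspartoacylase gene, at -1.15 (SE 0.08), Mal at -0.92 (SE 0.11) and Fa2h, a sphingolipid hydroxylase gene, at -0.61 (SE 0.05). That list was not called without each of 3 polysome arrays (adjusted p = 0.0577, 0.062 and 0.0742). Of 9 homeostatic microglia markers 7 fell and 0 rose (8 and 0 adjusted over the list alone). For this list the median was -0.28 relative to all genes (adjusted p = 0.0011, adjusted p = 0.13 with an estimated correlation), with P2ry12 at -0.85 (SE 0.09). Astrocyte markers were split, 6 higher and 5 lower of 15 (7 and 5 adjusted over the list alone, adjusted p = 0.49): Aldh1l1 rose by 0.55 (SE 0.07) while Aqp4 fell. Ribosomal protein genes (6 higher, 7 lower of 43; 6 and 6 adjusted over the list alone, adjusted p = 0.23) and proteasome genes (8 higher, 10 lower of 37; 8 and 10 adjusted over the list alone, adjusted p = 0.52) also went both ways.

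Limma called 4053 genes on polysomes, 1426 higher and 2627 lower (39.1% of genes), of which 42 rose and 28 fell at least 2-fold. The groups did not overlap for 46.3% of genes, where chance gives 10%. Among genes with 2 or more probe sets, 725 were called higher by the brightest, and the second was higher for 31.2% and lower for 10.2%. For 1006 called lower it was lower for 58.8% and higher for 1.4%. Of the calls, 35.2% were higher as deposited, 55.2% after either quantile normalization and 57.2% after median centring. Thus the excess of falls turned into an excess of rises, and 1400 genes were higher and 1699 lower in each of deposited, quantile and centred values. These changes moved with the Gapdh 3′ minus 5′ difference, which was 1.96 greater after injury on polysomes. The other controls changed by 1.58 for Actb, -0.04 for Pcx and -0.04 for Tfrc. Without injured polysome replicate 1 or 2, the arrays of low weight, 42.1% and 29.4% of calls were higher. With the spread taken from the polysome groups alone, limma called 2997 genes, 1036 higher and 1961 lower, and array weights gave 3600. In total RNA, the spread from its own groups gave 7005 genes and array weights 7171.

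**Figure D2:**
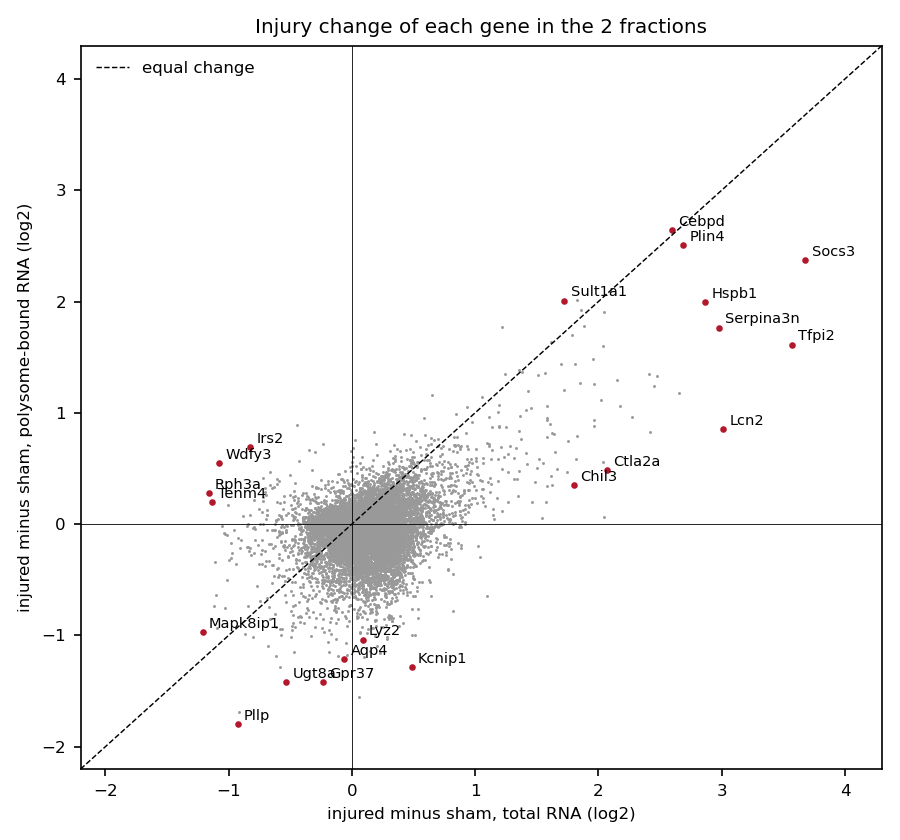
Change of each of the 10371 genes after injury (injured minus sham, log2) in total RNA (horizontal axis) and polysome-bound RNA (vertical axis); the dashed line marks equal change, and red points are named genes. Socs3 changed by 3.68 and 2.38, Cebpd by 2.60 and 2.64, and Aqp4 by -0.06 and -1.21.

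The interaction asked where the injury change on polysomes differed from that in total RNA. Some genes rose far less on polysomes than in total RNA. Lcn2 had an interaction of -2.16 (SE 0.47, limma adjusted p = 0.0023), with 3.01 in total RNA against means of 6.78 ± 0.38 and 7.63 ± 0.65 on polysomes (± SD, n = 3). Tfpi2 (-1.96, SE 0.46), the chemokine gene Cxcl2 (-1.59, SE 0.22), Ctla2a (-1.58, SE 0.24) and the leukocyte tetraspanin gene Cd53 (-1.49, SE 0.22) behaved alike. Slfn4 (-1.98, SE 0.32) was above every absent control on 0 of 3 arrays of either polysome group, so the size of its difference and its rank are not determined. Nor are those of Tfpi2 and Cxcl2, which were above every absent control on 0 of 3 sham arrays in either fraction. Other genes moved apart in direction: Igfbp7, an insulin-like growth factor binding protein gene, rose by 1.10 (SE 0.09) in total RNA and fell by 0.65 (SE 0.09) on polysomes (interaction -1.75, SE 0.13), and Kcnip1 rose by 0.48 and fell by 1.28 (-1.77, SE 0.10). ND5 (-1.61, SE 0.14) and the matrix gene Ogn (-1.60, SE 0.21) completed the largest negative values. Other probe sets of Kcnip1 ranged from -1.36 to 0.22 and those of Igfbp7 from -0.19 to 0.09.

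Other transcripts fell in total RNA but not on polysomes. Irs2, an insulin receptor substrate gene, fell by 0.82 (SE 0.10) in total RNA and rose by 0.69 (SE 0.10) on polysomes (interaction 1.52, SE 0.14, limma adjusted p = 1.1e-05), and the bromodomain gene Brd2 fell by 0.45 (SE 0.07) and rose by 0.89 (SE 0.07; interaction 1.34, SE 0.09). Wdfy3 (1.62, SE 0.20), Rph3a (1.44, SE 0.21), Tenm4 (1.33, SE 0.17), Atp8a1 (1.18, SE 0.15), Endod1 (1.14, SE 0.29), Sbno1 (1.13, SE 0.12), Psg28 (1.04, SE 0.15) and Pja2 (1.03, SE 0.10) were the others. Probe sets disagreed for several: the second one of Brd2 gave -0.17, those of Sbno1 -0.33 to 0.51 and those of Pja2 -1.29 and -1.03, and the mean of the Pja2 probe sets was -0.43. Psg28 was above every absent control on 0 of 6 polysome arrays, so its value and rank are not determined.

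Of the 37 lists, camera called 2 for the interaction, and between 2 and 6 with 1 array left out, 4 or 5 with the replicate number as a block and 10 with no filter. Proteasome genes were lower (24 lower and 1 higher of 37, 25 and 1 adjusted over the list alone), with a median of -0.12 relative to all genes (adjusted p = 0.028, adjusted p = 0.92 with an estimated correlation). Lymphocyte markers were higher (3 and 0 of 7; 2 and 0 adjusted over the list alone, adjusted p = 0.019, adjusted p = 0.79 with an estimated correlation). Psmd6, a proteasome subunit gene, had an interaction of -0.89 (SE 0.09) and the lymphocyte gene Cd4 one of 0.27 (SE 0.08). Neither list was called after quantile normalization (adjusted p = 0.6 and 0.46). Among lists not called as deposited, reactive astrocyte genes had 13 of 21 lower and 0 higher (13 and 0 adjusted over the list alone). The list median was -0.30 relative to all genes (adjusted p = 0.13), with Emp1 at -1.38 (SE 0.18) and Cd14 at -1.31 (SE 0.20). Monocyte and macrophage markers had 7 of 15 lower and 0 higher (7 and 0 adjusted over the list alone). This list's median was -0.57 relative to all genes (adjusted p = 0.064), with Chil3 at -1.45 (SE 0.22; above every absent control on 0 of 3 sham polysome arrays) and Lyz2 at -1.12 (SE 0.17). After quantile normalization both passed, at adjusted p = 0.0012 and 0.00038, but with an estimated correlation in the deposited values neither did (adjusted p = 0.918 each). Quantile normalization also brought calls for axon guidance genes (higher, adjusted p = 0.0046) and for cytokine, acute phase and endothelial activation genes (lower, adjusted p = 0.012, 0.03 and 0.03). As deposited these had adjusted p = 0.08, 0.34, 0.34 and 0.22, and adjusted p = 0.92, 0.92, 0.93 and 0.92 with an estimated correlation. Glucocorticoid-induced genes had 4 lower and 1 higher of 11 (4 and 1 adjusted over the list alone, adjusted p = 0.8), and Cebpd, Sult1a1 and Cdkn1a were not among those that differed. Sult1a1 had 0.28 (SE 0.12, limma adjusted p = 0.068) and Cdkn1a 0.18 (SE 0.15, limma adjusted p = 0.32).

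Limma called 5208 genes for the interaction, 1136 higher and 4072 lower (50.2% of genes), against an all-gene median of -0.16. Higher calls were 21.8% as deposited, 47.0% after quantile normalization, 47.8% within fractions and 64.1% after median centring, and 698 were higher and 1373 lower in each of deposited, quantile and centred values. Of the 4369 genes higher in total RNA, 2849 had a negative and 24 a positive interaction, and their median change was 0.33 in total RNA and 0.01 on polysomes. Of the 1873 lower ones, 923 had a positive and 61 a negative interaction. The total RNA change enters the interaction with a minus sign, so choosing genes by that change favours these signs. Genes called higher in both fractions numbered 1035, where independent lists of these sizes share 601, and 402 were lower in both, where independent lists share 474. Across genes, which are not independent replicates, Pearson r was 0.37 (jackknife SE 0.10) and the total least squares slope of the polysome change on the total change 0.65 (SE 0.17). Of the genes called higher and lower in total RNA, 51.6% and 61.0% had the same sign on polysomes. Among the 147 genes changed at least 2-fold in total RNA it was 95.2%, with a median ratio of 0.49, but 132 of these were rises, and the 15 falls had a polysome median of -0.10 (quartiles -0.69 and 0.08). Choosing genes by their change in total RNA also favours a smaller change on polysomes, and so a lower ratio.

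**Figure D3:**
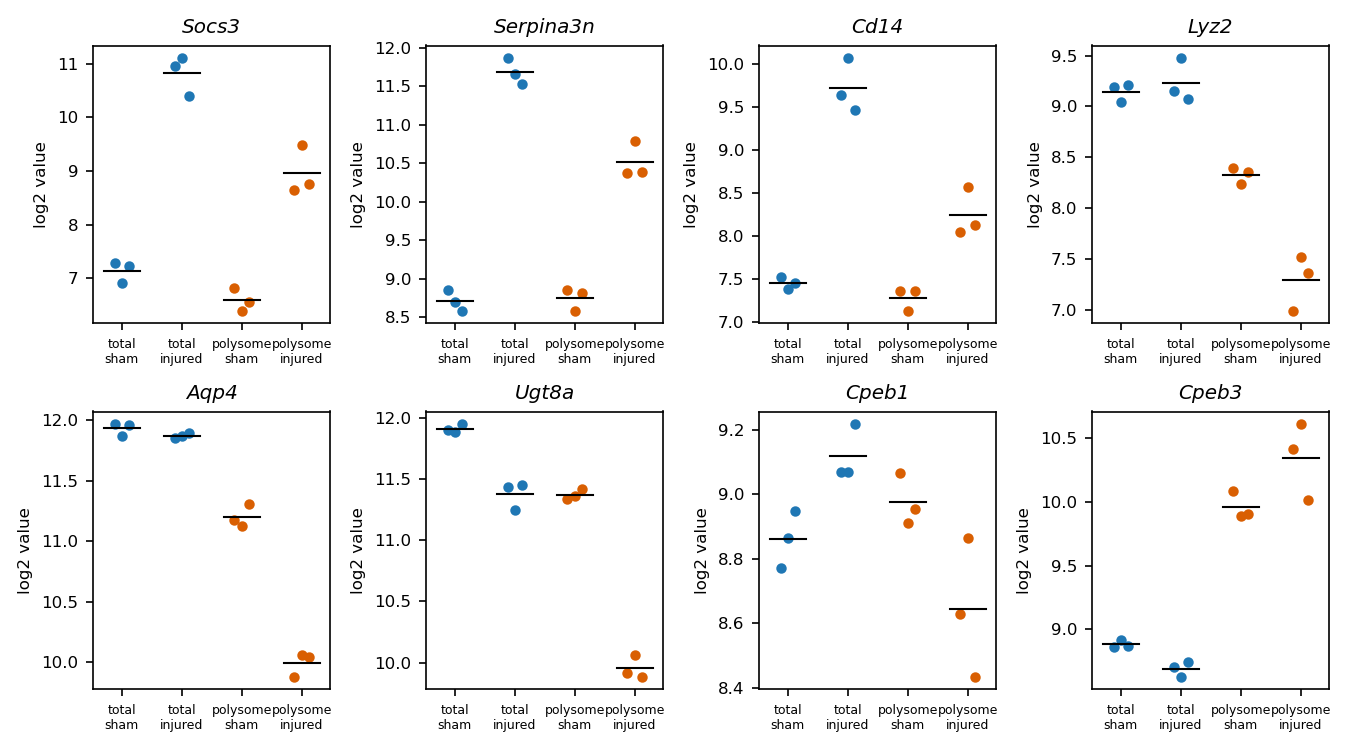
Deposited log2 values of 8 genes on each array (points) with group means (lines); blue, total RNA; orange, polysome-bound RNA. Aqp4 averaged 11.93 and 11.87 in sham and injured total RNA against 11.20 and 9.99 on polysomes.

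Polysome-bound was compared with total RNA within each operation to show which transcripts were enriched on or depleted from polysomes. In sham cord, noncoding RNAs were among the most depleted transcripts. Xist, the noncoding RNA of X inactivation, was 6.70 ± 0.07 on polysomes and 11.17 ± 0.06 in total RNA (mean ± SD, n = 3; log2 -4.47, SE 0.06, limma adjusted p = 1.5e-15). Mtm1 (-3.38, SE 0.11), the myelin gene Mobp (-3.24, SE 0.11), Neat1 (-2.80, SE 0.13) and Snhg11 (-2.64, SE 0.12) followed. The largest enrichments were those of the tubulin gene Tubb2b (2.01, SE 0.08), Ampd2 (1.87, SE 0.07), Ppig (1.55, SE 0.12), Timm10 (1.44, SE 0.11) and Bcas2 (1.44, SE 0.09). In injured cord Xist (-4.48, SE 0.06), ND5 (-3.90, SE 0.10), Neat1 (-3.60, SE 0.13), Mobp (-3.43, SE 0.11) and Slfn4 (-3.42, SE 0.23) were lowest. The polysome values of Slfn4 lay at background, above every absent control on 0 of 3 injured arrays, so its depletion and rank are not determined. Ppig (2.51, SE 0.12), Brd2 (2.34, SE 0.07), Rph3a (2.26, SE 0.15), Naa15 (2.11, SE 0.08) and Camkk2 (2.09, SE 0.07) were highest. The other probe set of Brd2 gave -0.42, and the 3 others of Naa15 -1.38 to -0.92.

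Relative to an all-gene median of -0.30 in sham and -0.41 in injured cord, the following groups stood apart. All 9 nuclear-retained noncoding RNAs were lower in both cords (9 and 9 adjusted over the list alone). In sham cord their median was -1.38 relative to all genes (camera adjusted p = 0.0083, adjusted p = 0.54 with an estimated correlation), and in injured cord -1.08 (adjusted p = 0.031, adjusted p = 0.86 with an estimated correlation). All 14 endothelial and barrier markers, 43% of them above the absent controls, were lower in both (14 and 14 adjusted over the list alone). The medians were -1.18 and -1.40 relative to all genes (adjusted p = 0.00018 and 0.0005, adjusted p = 0.54 and 0.86 with an estimated correlation), with the transporter gene Slco1a4 at -2.63 and -2.82 (SE 0.07 each). Of 18 meningeal, pericyte and matrix genes 16 were lower in sham and 17 in injured cord (16 and 17 adjusted over the list alone). The medians were -0.63 and -1.04 relative to all genes (adjusted p = 0.026 and 0.024, adjusted p = 0.77 and 0.86 with an estimated correlation), with the pericyte gene Rgs5 at -2.64 and -3.16 (SE 0.09 each). These 3 lists kept their calls in both cords after quantile normalization. In sham cord 11 of 12 neutrophil markers were lower (11 adjusted over the list alone, adjusted p = 0.049, adjusted p = 0.69 with an estimated correlation, and 0.0529 to 0.0685 without each of 4 single arrays), as were 139 of 181 zinc finger genes, with 13 higher (139 and 13 adjusted over the list alone, adjusted p = 0.0073, adjusted p = 0.69 with an estimated correlation). After quantile normalization the median of the zinc finger list was 0.04 and it was not called (adjusted p = 0.99).

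Lists called higher on polysomes relative to all genes in both cords were those of the proteasome, the respiratory chain, heat shock and neurons. Brighter genes in general lay higher on polysomes as deposited. In sham cord the median was -0.57 for the dimmest 1038 genes and 0.25 for the brightest 1037, and in injured cord -0.42 and -0.05. After quantile normalization these were 0.02 and 0.10 in sham and 0.05 and 0.09 in injured cord. How far brightness accounts for the deposited values of these lists was not tested. Proteasome genes were higher in 28 and lower in 5 of 37 cases in sham cord and in 17 and 12 in injured cord (28 and 5, then 17 and 12 adjusted over the list alone). The medians were 0.77 and 0.48 above all genes (camera adjusted p = 1.4e-12 and 1.1e-07, adjusted p = 0.54 and 0.86 with an estimated correlation), with Psmd13 at 1.15 and 1.42 (SE 0.06 each). Respiratory chain genes were higher in 50 and lower in 7 of 77 cases in sham cord and in 27 each in injured cord (50 and 6, then 27 and 27 adjusted over the list alone). The medians were 0.63 and 0.43 above all genes (adjusted p = 6.5e-13 and 1.1e-07, adjusted p = 0.69 and 0.86 with an estimated correlation). In injured cord the median of that list was 0.02, its mean -0.01 and its tested direction higher. Heat shock genes were higher in 10 and lower in 0 of 13 cases in sham cord and in 7 and 3 in injured cord (10 and 0, then 7 and 2 adjusted over the list alone). The medians were 0.72 and 0.60 above all genes (adjusted p = 4.7e-06 and 0.00034, adjusted p = 0.3 and 0.74 with an estimated correlation), with the mitochondrial chaperone gene Hspd1 at 0.84 and 0.54 (SE 0.06 each). Neuron markers were higher in 9 and lower in 7 of 21 cases in sham cord and in 8 and 10 in injured cord (9 and 7, then 8 and 10 adjusted over the list alone). The medians were 0.41 and 0.42 above all genes (adjusted p = 0.0057 and 0.0023, adjusted p = 0.54 and 0.86 with an estimated correlation), with the neuronal tubulin gene Tubb3 at 1.43 and 1.40 (SE 0.06 each). Regeneration-associated genes were called higher in sham cord, with 7 higher and 6 lower of 21 (7 and 6 adjusted over the list alone, adjusted p = 0.026, adjusted p = 0.77 with an estimated correlation). After quantile normalization the neuron list lost its call in both cords (adjusted p = 0.37 and 0.39), the regeneration list in sham (0.074), and the heat shock and respiratory chain lists in injured cord (0.12 and 0.15). Ribosomal protein genes lay the other way, with 2 higher and 30 lower of 43 in sham and 2 and 38 in injured cord (the same numbers adjusted over the list alone). The list was not called as deposited (adjusted p = 0.18 and 0.062, adjusted p = 0.86 and 0.89 with an estimated correlation) and was lower after quantile normalization (adjusted p = 1.7e-08 and 1.7e-07). Synaptic receptor and channel genes had 0 higher and 16 lower of 22 in sham and 3 and 17 in injured cord (the same numbers adjusted over the list alone, adjusted p = 0.2 and 0.68, and 0.027 and 0.4 after quantile normalization). That normalization also brought further list calls, none of which passed with an estimated correlation in the deposited values. Astrocyte markers were called lower in both cords (adjusted p = 7.1e-05 and 0.00035). In sham cord homeostatic microglia markers (0.0097) and elongation genes (0.035) were called lower and cell cycle genes higher (0.035). In injured cord cytokines (0.0032), reactive astrocyte genes (0.0015), monocyte markers (0.00065) and endothelial activation genes (0.0032) were called lower.

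Limma called 8306 genes between fractions in sham cord, 2175 higher on polysomes and 6131 lower (80.1% of genes), and 8952 in injured cord, 1413 higher and 7539 lower (86.3%). The groups did not overlap for 86.2% and 84.8% of genes, where chance gives 10%. Some genes had 2 or more probe sets. Where the brightest was called higher (1131 genes in sham, 749 in injured cord), the second was higher for 39.2% and 31.8%. It was lower for 32.4% and 45.4%. Where the brightest was called lower (1963 and 2615 genes), the second was lower for 87.7% and 85.6% and higher for 3.5% and 5.8%. The balance depended on the scaling and reversed only under some: 26.2% of calls were higher in sham cord as deposited, 56.8% after quantile normalization, 19.3% within fractions and 49.1% after centring, and in injured cord 15.8%, 55.7%, 21.0% and 60.3%. The Gapdh 3′ minus 5′ difference moved with these comparisons and was 0.64 greater on polysomes in sham and 1.43 in injured cord (0.22 and 1.46 for Actb). The other controls gave 0.34 and 0.02 for Pcx and -0.68 and -0.51 for Tfrc. In each of deposited, quantile and centred values, 1982 genes were higher and 2338 lower in sham cord, and 1409 and 2818 in injured cord. Cpeb3 was higher on polysomes by 1.08 (SE 0.11) in sham and 1.65 (SE 0.11) in injured cord, and Cpeb1 had 0.12 (SE 0.09, limma adjusted p = 0.27) and -0.48 (SE 0.09, limma adjusted p = 0.00025). The latter was 0.04 after median centring.

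**Figure D4:**
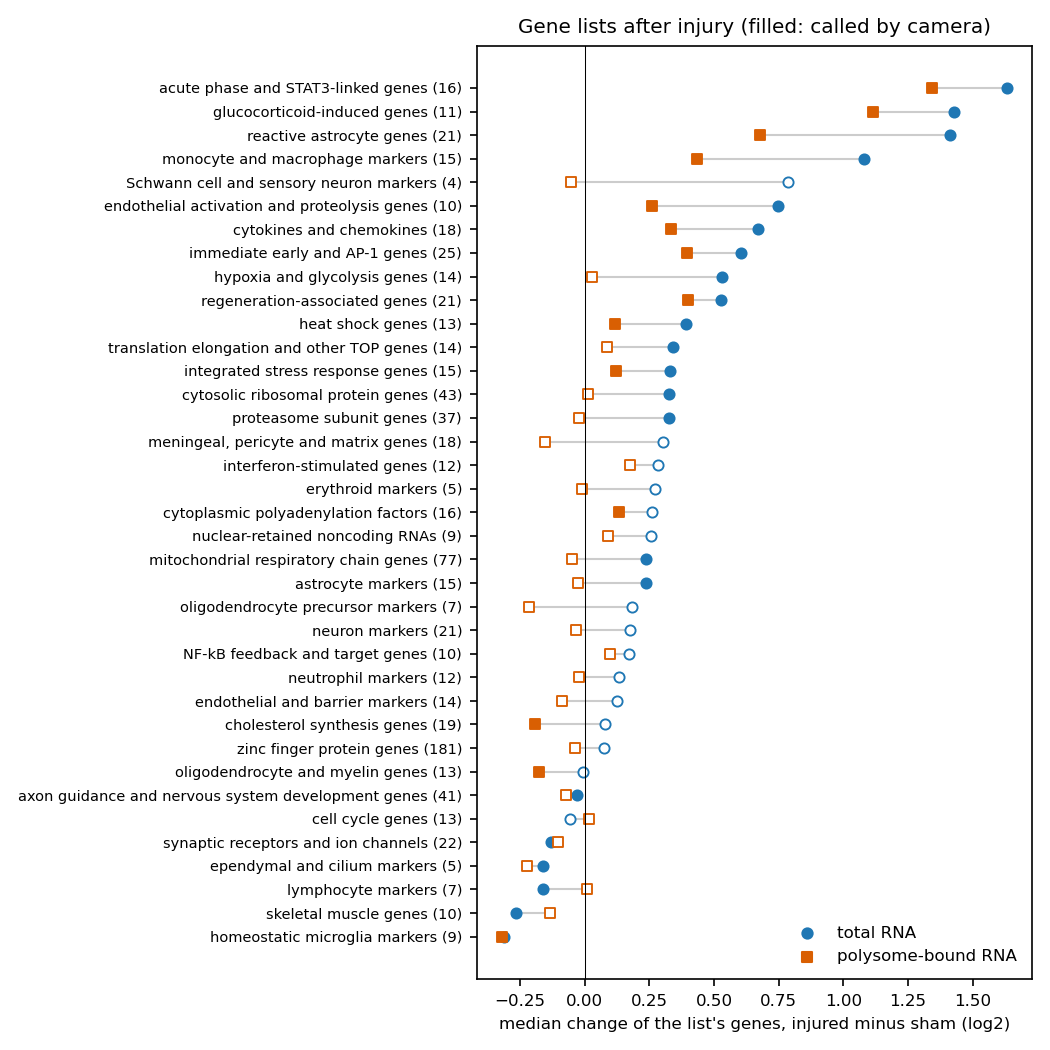
Median change of the genes of each of 37 lists after injury (injured minus sham, log2; number of genes in brackets) in total RNA (blue circles) and polysome-bound RNA (orange squares); filled symbols were called by camera at the preset correlation. Acute phase genes had the highest median in total RNA, 1.63, and homeostatic microglia markers the lowest, -0.31.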

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

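Results are given here where the injury change differed between total and polysome-bound RNA by a test of that difference, or where control probe sets outside the gene comparisons changed. All tests of explanations in this part were chosen after the results they measure had been seen. Limma called 5208 genes for the difference. Higher on polysomes relative to total RNA were Wdfy3 (1.62), Irs2 (1.52), Rph3a (1.44), Brd2 (1.34), Tenm4 (1.33), Atp8a1 (1.18), Endod1 (1.14), Sbno1 (1.13), Psg28 (1.04), Pja2 (1.03), the potassium channel genes Kcna1 (0.96) and Kcna2 (0.76), Sesn2 (0.65), Cpeb3 (0.58) and Sema6a (0.43). The value of Psg28 is not determined, as it lay at background on all 6 polysome arrays. Other probe sets of Brd2, Sbno1 and Pja2 gave weaker differences or the other sign, as stated above.

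Lower on polysomes relative to total RNA were Lcn2 (-2.16), Slfn4 (-1.98), Tfpi2 (-1.96), Kcnip1 (-1.77), Igfbp7 (-1.75), ND5 (-1.61), Ogn (-1.60), Cxcl2 (-1.59), Ctla2a (-1.58) and Cd53 (-1.49). Inflammatory and stress genes in the same direction were Ptgs2 (-1.48), Chil3 (-1.45), Emp1 (-1.38), Cd14 (-1.31), Socs3 (-1.30), Serpina3n (-1.21), Lyz2 (-1.12), Ccl3 (-0.80), Adm (-0.76), Dusp1 (-0.75), Icam1 (-0.65) and Tsc22d3 (-0.55). Glial, lipid and matrix genes were Mal (-1.18), Aqp4 (-1.15), Fdps (-1.14), Nsdhl (-1.005), Ugt8a (-0.89) and Col4a2 (-0.86). Rplp0 (-0.90), the glycine receptor gene Glrb (-0.84), Sema5a (-0.77), Ndufb2 (-0.85), Rpl6 (-0.68), Eif3h (-0.65) and Cpeb1 (-0.59) completed the set. Slfn4, Tfpi2, Cxcl2, Ptgs2, Chil3, Ccl3, Adm and Icam1 each lay at background on all 3 arrays of at least 1 group, so the sizes of these differences are not determined. Other probe sets of Kcnip1 and Igfbp7 gave weaker differences or the other sign. The difference of Cpeb1 was not called after quantile normalization. Among the controls, the 3′ minus 5′ difference of Gapdh was greater after injury by 1.17 in total and 1.96 in polysome-bound RNA, and that of Actb by 0.34 and 1.58. In total RNA it changed by 0.29 for Pcx and by -0.21 for Tfrc. The median of the spike-in controls changed with injury by -0.48 in total and -0.32 in polysome-bound RNA, and in total RNA the 18S control (-0.55) and the highest absent control (-0.19) were lower too. In each of these the injured and sham arrays did not overlap.

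With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For each of the 5 comparisons 1 of the 10 splits, the real one, gave as many genes. The real splits called 6242 (injury, total RNA), 4053 (injury, polysomes), 5208 (difference between fractions), 8306 (fractions, sham) and 8952 (fractions, injured), and the highest other split called 0. Every other split mixed the real groups, so the real difference entered the spread. The 0 therefore does not measure what chance would give.

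The 132 genes that rose at least 2-fold in total RNA rose less on polysomes, with a median difference of -0.74 (quartiles -1.06 and -0.41) and 94 called smaller against 0 called larger. The 3 other scalings tried did not account for all of it: at least 75 stayed called smaller under quantile normalization over all arrays or within fractions and under median centring (medians -0.64, -0.55 and -0.50). Values near background did not account for the 55 genes over 2 log2 units above the absent controls in each group (median -0.73, quartiles -1.01 and -0.39; -0.51, -0.40 and -0.49 under the 3 other scalings), but for the other 77 (median -0.75) this stayed open. RNA shortening also stayed open, because the Gapdh 3′ minus 5′ change was 0.79 greater on polysomes than in total RNA. The same value was 1.24 for Actb, 0.16 for Tfrc and -0.32 for Pcx, so the controls disagreed. The choice of genes by their rise in total RNA favours a smaller rise elsewhere: the 42 genes picked by a 2-fold rise on polysomes had a median of -0.24, and of -0.01 after median centring.

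Of 13 oligodendrocyte and myelin genes, 5 fell on polysomes with a median of -0.92. The other 8 members had a median of 0.04. The 5 were picked by their call on polysomes, which sets them apart from the others and favours a smaller change in total RNA. The members did not share 1 common change: 11 of the 13 lay over 2 SE from the weighted mean of the list, 6 above and 5 below it. Without Mbp and Cnp, which lay over 13 log2 units where arrays can saturate, it was 11 of 11. That test covers only equal measured changes, so a loss of oligodendrocyte transcripts as part of the cause stayed open. Quantile normalization did not remove the call of the list (camera adjusted p = 0.00268). It also brought a lower call of the list in total RNA (camera adjusted p = 0.041). The difference between fractions was not called for the list (camera adjusted p = 0.22 as deposited and 0.31 after quantile normalization). RNA shortening in the injured polysome samples stayed open: the median change of the same 5 genes in total RNA was -0.11. The 3′ minus 5′ change was greater on polysomes for Gapdh and Actb, but not for Pcx (0.29 in total and -0.04 in polysome-bound RNA). A change in the polysome loading of these transcripts after injury may also apply and was not tested apart from it.

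The 1873 genes lower in total RNA had a median of -0.24 there and of -0.0285 (quartiles -0.14 and 0.04) on polysomes. Their choice by a fall in total RNA favours a smaller fall elsewhere. RNA shortening stayed open: the 3′ minus 5′ difference rose more on polysomes for Gapdh and Actb, but for Pcx it rose by 0.29 in total RNA and changed by -0.04 on polysomes, so the controls disagreed. Array scaling stayed open. At least 976 stayed called lower in total RNA under 3 other scalings (medians -0.16, -0.17 and -0.39), but all 3 align the medians or distributions of arrays. They cannot exclude a shift such as that of the spike-in median, which changed by -0.48 with injury in total RNA. For the dimmest 1038 genes the median went from -0.15 to -0.01 after quantile normalization, and for the brightest 1037 from 0.27 to 0.01. Values near background stayed open. Of these genes 1606 lay within 2 log2 units of the absent controls in at least 1 group, with a median difference between the fractions of 0.207. For the other 267 it was 0.127 as deposited, with quartiles of -0.10 and 0.37 that span 0. It was 0.45 after quantile normalization, 0.42 within fractions and 0.37 after centring, each with a lower quartile above 0 (0.26, 0.19 and 0.13), so background was argued against for these genes only under those scalings. In the other direction, the 28 genes that fell at least 2-fold on polysomes had a median of -0.12 in total RNA as deposited, -0.42 after quantile normalization, -0.40 within fractions and -0.27 after centring. Another candidate explanation is that transcripts off polysomes were lost while those on polysomes stayed, which these arrays do not measure directly.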

How the results depend on the processing

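The direction of most results of named genes held: leaving out 1 array gave 4670 results alike, 58 that lost and 9 that gained a call. With the probe set of each gene kept as chosen on all arrays, an alternative chosen after seeing the data, 3 of the 58 kept their call, all of them Stat3 in total RNA (1.14 to 1.23), and the other 55 had used the same probe set. Each named gene result counted once in the other settings. Under quantile normalization over all arrays 363 were alike, 27 lost and 5 gained a call. Under median centring 381 were alike, 4 lost and 8 gained a call, and 2 reversed. Unless stated, the cause of a change was not tested.

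Counts by direction moved with the scaling. Quantile normalization over all arrays gave 2365 genes higher in total RNA, 2314 higher on polysomes, 1874 lower for the difference between fractions, 3963 higher and 3019 lower between fractions in sham cord, and 4239 and 3365 in injured cord. Within each fraction it gave 3917 genes in total RNA, 2194 higher, with 2437 higher on polysomes, 1829 lower for the difference and a slope of 0.870. Median centring gave 2322 higher and 3473 lower in total RNA, 2464 higher on polysomes, 3327 higher and 1865 lower for the difference, 3904 and 4053 in sham cord, and 4523 and 2977 in injured cord. Genes called alike in deposited, quantile and centred values, an alternative chosen after seeing the data, numbered 1667 higher and 976 lower in total RNA, 1699 lower on polysomes, 698 higher and 1373 lower for the difference, and 2338 and 2818 lower between fractions in sham and injured cord.

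With more genes tested, no filter gave 2865 lower in total RNA. Testing every probe set of these genes gave 1727 higher for the difference. With fewer genes tested, the filter at the array median gave 657 lower in total RNA, 438 higher for the difference, 3493 and 4952 lower between fractions in sham and injured cord, and a slope of 0.893. Background limits the lists whose genes mostly lay at it: 10% of skeletal muscle, 28% of cytokine, 29% of lymphocyte, 38% of cell cycle, 40% of monocyte, 40% of erythroid and 43% of endothelial and barrier genes lay above the absent controls. A minimum of 2-fold by construction left 147 genes in total RNA (132 higher, 15 lower), 70 on polysomes (42, 28), 133 for the difference (14, 119), 561 in sham cord (84, 477) and 1523 in injured cord (114, 1409).

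Camera with an estimated correlation called 0 lists in total RNA, 1 on polysomes, 0 for the difference and 0 and 0 between fractions in sham and injured cord. The rotation test fry called 22 for the difference, 32 in sham and 36 in injured cord. For the difference, lists numbered 10 with no filter, 5 with the mean of probe sets, 6 after quantile normalization, 5 within fractions and 5 after centring. In injured cord there were 11 within fractions and 16 after centring.

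Among named genes, Cpsf3 reversed on polysomes without shared probe sets (-0.0655) and Pja2 for the difference with the mean of probe sets (-0.43). Between fractions in injured cord, Naa15 (-0.33) and Psmd4 (-0.0505) reversed with that mean, and Cpeb1 (0.0363) and Cpeb4 (0.17) after centring. Over all genes called as deposited, quantile normalization over all arrays called 988 of 8306 the other way between fractions in sham cord. In injured cord it was 1598 of 8952. Median centring gave 37 and 1707 in the same order. For injury in total RNA, 3122 of 6242 kept their call after that quantile normalization and 8 were called the other way. For the difference, 2475 of 5208 kept it and 1 was called the other way. The respiratory chain list turned lower in total RNA after quantile normalization over all arrays (adjusted p = 0.302) and within fractions (adjusted p = 0.292).

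Leaving out 1 array gave 5203 to 6782 genes in total RNA (3623 to 4798 higher, 1551 to 1984 lower), 3200 to 4160 on polysomes (1091 to 1635, 2109 to 2936), 4445 to 5681 for the difference (906 to 1168, 3514 to 4513), 7919 to 8658 in sham cord (1974 to 2362, 5862 to 6296) and 8624 to 8906 in injured cord (1283 to 1560, 7275 to 7605). Pearson r ranged from 0.30 to 0.44 and the slope from 0.55 to 0.76. Lists ranged from 20 to 22 in total RNA, 10 to 17 on polysomes, 2 to 6 for the difference, 9 to 11 in sham and 7 to 9 in injured cord. For the difference there were 4 without sham total replicate 1, injured total replicate 3 or sham polysome replicate 2, 6 without sham polysome replicate 3 and 5 without injured polysome replicate 3.

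The labels number replicates alike across groups. After group means were removed, equal-number total and polysome arrays correlated across genes at 0.23, 0.18 and 0.17 in sham and -0.10, 0.20 and 0.10 in injured cord. With the number as a replicate block joining total and polysome arrays, limma called 6243 genes in total RNA, 4055 on polysomes, 5006 for the difference, 8252 in sham and 8890 in injured cord, and camera 4 lists for the difference. With the number as a replicate block over all groups the counts were 6109, 3917, 5065, 8262 and 8909, and 5 lists for the difference.

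The analysis of cytoplasmic polyadenylation element motifs and its 2 alternatives was not run.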

Other observations

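Several lists were not called by camera after injury in either fraction. In total RNA their adjusted p were 0.45 for NF-kB target genes (5 higher, 1 lower of 10, with Bcl3 at 1.11, SE 0.14), 0.061 for interferon-stimulated genes (8 and 0 of 12, with Gbp2 at 1.62, SE 0.14), 0.93 for oligodendrocyte precursor markers (3 and 2 of 7, with Pdgfra at 0.99, SE 0.10) and 0.49 for neutrophil markers (6 and 4 of 12, with S100a9 at 1.59, SE 0.27, and Camp at -0.57, SE 0.08). They were 0.85 for erythroid markers (3 and 1 of 5), 0.93 for endothelial and barrier markers (5 and 3 of 14, with Cdh5 at 0.72, SE 0.11), 0.23 for meningeal, pericyte and matrix genes (10 and 2 of 18, with the matrix gene Tnc at 1.34, SE 0.11) and 0.18 for Schwann cell and sensory neuron markers (3 and 0 of 4). Cell cycle genes had 0.16 (2 and 2 of 13), the noncoding RNA list 0.31 (6 and 1 of 9) and zinc finger genes 0.8 (67 and 27 of 181). Cholesterol synthesis genes (0.37; 5 and 4 of 19) and oligodendrocyte genes (0.26; 4 and 3 of 13) were called lower on polysomes. After quantile normalization both were called lower in total RNA too (adjusted p = 0.00044 and 0.041), and interferon-stimulated genes were called higher there (0.0019). With an estimated correlation in the deposited values, cholesterol, oligodendrocyte and interferon genes had adjusted p = 0.83, 0.69 and 0.56 there. The difference between fractions was not called for cholesterol or oligodendrocyte genes as deposited (0.13 and 0.22).

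On polysomes the same lists had adjusted p of 0.25 (NF-kB, 2 higher and 1 lower), 0.059 (interferon, 4 and 2), 0.52 (oligodendrocyte precursors, 1 and 3, with Olig2 at -0.57, SE 0.08), 0.36 (neutrophil, 4 and 2), 0.83 (erythroid, 1 and 1), 0.41 (endothelial and barrier, 0 and 4), 0.36 (meningeal and matrix, 2 and 6, with Col1a1 at -0.83, SE 0.08) and 0.69 (Schwann, 1 and 1). They were 0.46 for cell cycle (1 and 0), 0.24 for the noncoding RNA list (2 and 0) and 0.92 for zinc finger genes (21 and 46). Lists called in total RNA had here 0.084 for hypoxia (4 and 2, with Hk2 at 1.14, SE 0.09), 0.51 for axon guidance (1 and 11, with Fgfr2 at -1.01, SE 0.07) and 0.23 for synaptic genes (1 and 7, with Glrb at -0.51, SE 0.07). Lymphocyte (0.85; 0 and 0), ependymal (0.26; 0 and 3), muscle (0.89; 0 and 0), elongation (0.22; 4 and 3) and respiratory chain genes (0.78; 4 and 19, with Ndufb2 at -0.59, SE 0.07) were not called either, nor were neuron markers (0.69; 6 and 6). After quantile normalization the respiratory chain list was called lower on polysomes (adjusted p = 0.016, and adjusted p = 0.97 with an estimated correlation in the deposited values). The list median, mean and tested direction differed in sign for 6 lists in total RNA, 7 on polysomes, 12 for the difference between fractions and 9 and 9 between fractions in sham and injured cord.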
